A study of Bos taurus with 6 samples.

How the data were processed

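The series holds 6 RNA-seq libraries of bovine (Bos taurus) blastocysts at day 7 after in vitro production. Each library was made from a pool of embryos. In 3 libraries the embryos had been treated with beta-hydroxybutyrate (BHB), a ketone body, and in 3 control libraries they had not. The oocytes came from slaughterhouse material, and the dose of BHB, the time of exposure and the number of embryos per pool are not given in the sources used here. Per the labels' protocols, total RNA was treated with DNase, libraries were made from polyadenylated RNA with a stranded kit, and all libraries were sequenced as paired ends in 1 lane. Samples were assigned to a group by the treatment named in their labels. The labels give no replicate numbers, so the numbers 1 to 3 used here follow the order of deposit within each group. Nothing says that the pools came from separate batches of embryos, so p-values measure the spread between these libraries.

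The authors deposited 2 tables, 1 with whole-number counts per gene for the 6 libraries and 1 with the results of their own comparison. Per the submitters' processing notes, STAR, featureCounts and DESeq2 were used; their versions, the genome build, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The count columns are not normalized. The authors' deposited table of results (called the authors' deposited table below) holds a mean count on a linear signal scale, a log2 fold change, its error, a test statistic (a score), a p-value and an adjusted p-value for each gene. Its log2 fold change is control over BHB, as its sign against the group means of the counts shows, and is given here with the sign turned where a direction is named. The count table holds 12826 genes, each named by a gene symbol (some with a numbered suffix), a LOC placeholder or a locus tag, and no row without a gene name. The smallest total of any gene over the 6 libraries was 38 counts, so genes with fewer counts are not analysed here. Of the names, 12153 are symbols or locus tags of the ARS-UCD2.0 gene table, 198 are older symbols in it and 475 were not matched. That table was used for names alone, and no coordinates are given because no build is named.

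Totals ran from 6440732 to 8176648 counts per library. Counts were normalized with edgeR's TMM factors. The filterByExpr function of edgeR with the 2 groups left 12732 genes for testing and removed 94. BHB was compared with control by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05, with no covariate (R 4.3.3, edgeR 4.0.16). DESeq2 1.42.0 (Wald test) and limma 3.58.1 (voom) were run as alternatives. Levels are given as CPM (counts scaled to a fixed total) on TMM-scaled library sizes, as mean ± SD over 3 libraries, and fold changes as log2 of BHB over control with the standard error (SE). Gene lists were tested with limma's camera on log2 CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Before the data were examined, 34 lists were fixed from general knowledge of embryo lineages, metabolism, chromatin, stress, the cell cycle and cell types that a pool could also hold. Of these, 31 had at least 5 tested genes and were tested.

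The naming rule was also fixed before the data were examined. It takes the 10 genes with the largest fold change in each direction past the threshold, with a mean log2 CPM of at least 1 and groups that do not overlap, or, where fewer than 5 pass, the 5 genes with a symbol and the smallest p, said not to have passed. It adds up to 4 members of each list past the threshold or, if none passed, up to 2 with the smallest p, and a fixed set of ketone body, lineage and chromatin genes, of which SOX2 was not among the genes of the table. Some genes that the rule takes are not reported here. Other genes named below were chosen after their values were seen.

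The p-values in the authors' deposited table were compared with refits of the counts. DESeq2's likelihood ratio test of a model with 3 pairs of libraries and treatment against a model with neither gave the deposited p-value within 1e-06 in 99.98% of genes and the log2 fold change within 0.001 in 100% of genes, when control 1 was paired with BHB 1, control 2 with BHB 2 and control 3 with BHB 3. The other 5 pairings of control with BHB libraries gave the deposited p-value in 0 to 0.398% of genes. The pairing used here comes from that refit and is not stated in the labels. Over genes, the deviations of the 2 libraries of a pair from their group means correlated at 0.46, 0.32 and 0.33 in the 3 pairs, and those of libraries from different pairs at -0.30 to -0.004. The deviations of a group sum to 0, so positive values within pairs force negative ones between pairs on average. The negative values are thus no separate evidence. Correlations over genes describe these libraries, since genes are not independent replicates. Fits with the pair as a replicate block were therefore added after the data had been seen, and their values stand beside the results they change. The refitted statistic was split into a pair part (pair against neither, 2 degrees of freedom) and a treatment part (treatment given pair, 1 degree of freedom).

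The tests were checked on simulated counts drawn from means fitted to the real libraries, with 200 genes changed by known folds. Without pair differences, edgeR called 6.25% of genes changed 1.5-fold, 40.8% of those changed 2-fold, 88.9% of those changed 4-fold and 97.7% of those changed 8-fold, and DESeq2's Wald test without a block called 14%, 50%, 84% and 86%. With the fitted pair differences, edgeR called 2.08%, 12.2%, 82.2% and 87.2% of them without a block, and 31.3%, 69.4%, 97.8% and 97.9% with the replicate block. The blocked DESeq2 Wald test called 22%, 58%, 82% and 88% of them. The percentages of edgeR are over the changed genes that its filter kept (12381 genes tested without pair differences, 12390 with them). Those of DESeq2 are over all changed genes (12732 tested), so percentages of the 2 tools cannot be compared directly. Among unchanged simulated genes, edgeR called 13 and DESeq2's Wald test 22 without pair differences. With pair differences, edgeR called 0 without a block and 20 with it, and the blocked DESeq2 test called 4. With the fitted pair differences and no treatment effect, the joint test of pair and treatment called 1321 genes and the test of treatment given pair called 0; these simulated pair differences include noise and are therefore too large. For 2 lists shifted 1.3-fold, camera with the preset correlation called both, fry called 1 and camera with an estimated correlation called 0. Simulated genes were drawn independently, whereas the lists called below had estimated correlations of 0.16 to 0.77 without the block. The simulation therefore cannot show that the preset correlation suits those lists.

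No library was a copy of another. The chi-square of the counts of any 2 libraries over its degrees of freedom was 8.79 to 29.1, where sampling noise alone gives about 1. Alternatives covered the normalization, the filter on low counts, the test, the threshold, leaving out each library, the correlation in the list test and the replicate block. Leaving out 1 library was done without the block and keeps its partner in the other group, so such fits mix pair with treatment. A planned covariate made of Y-linked genes was not run because 0 genes of that list were in the table.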

Results

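The transcriptomes of pooled bovine day 7 blastocysts cultured with BHB (n = 3 libraries) or without it (n = 3 libraries) were compared to ask which genes and pathways of the preimplantation embryo differ with this ketone body. Total counts were 7925889, 7962872 and 8176648 in control libraries 1 to 3 and 7348949, 7238259 and 6440732 in BHB libraries 1 to 3. The mean total was 8021803 ± 135369 (SD, n = 3) in controls and 7009310 ± 495506 (SD, n = 3) with BHB. Mitochondrial transcripts took 9.74% ± 0.83 (SD, n = 3) of control counts and 8.94% ± 0.12 (SD, n = 3) of BHB counts.

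The largest separation among the libraries was of pair 1 from the others, not of treatment. Pair accounted for 57.5% of the variance of log2 CPM with 2 degrees of freedom, treatment for 16.6% with 1, and 25.9% with 2 was left. These shares were not tested, and with so few degrees of freedom each source takes a share even without an effect. The first principal component held 36.7% of the variance and set both libraries of pair 1 apart from the other 4. Pairs 2 and 3 overlapped on it (11.4 and 21.7 in pair 2, 19.5 and 24.9 in pair 3) and parted on the second component (40.4 and 11.3 against -17.4 and -23.6). With treatment in the model, edgeR's quasi-likelihood test called 524 genes between pairs. Among those with the smallest adjusted p were the collagen gene COL5A2 (adjusted p = 9.28e-05), the granzyme gene GZMB, which encodes a cytotoxic protease (adjusted p = 0.00081), GRP, which encodes gastrin-releasing peptide (adjusted p = 0.00086), and PAG2, a pregnancy-associated glycoprotein of the trophoblast (adjusted p = 0.0016). PAG genes form a large family of similar sequences, so the level of PAG2 is uncertain.

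**Figure D1:**
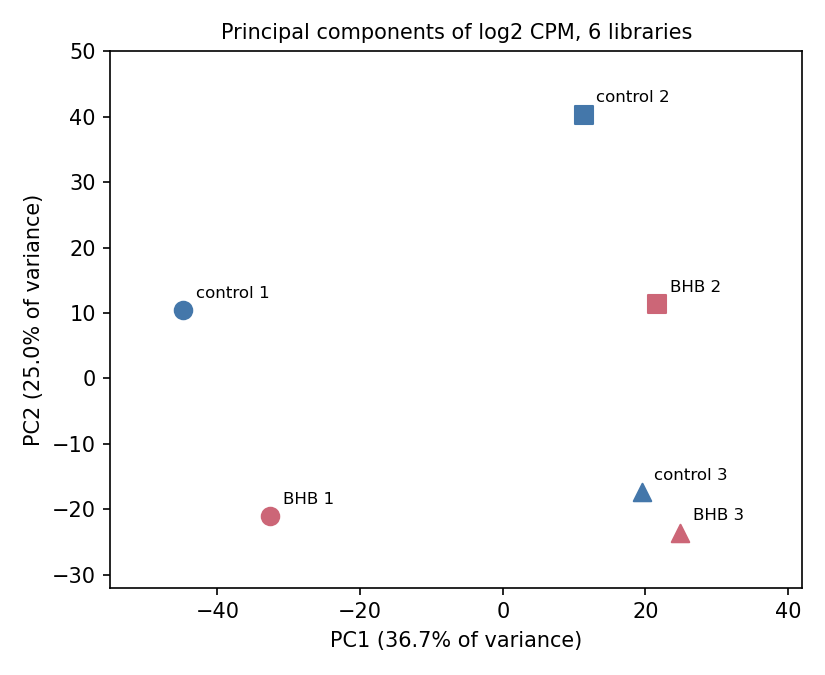
Each point is 1 library on the first 2 principal components of log2 CPM (axes give the share of variance); blue is control, red is BHB, and circles, squares and triangles are pairs 1, 2 and 3. The first component, with 36.7% of the variance, holds both libraries of pair 1 at negative values and the other 4 libraries at positive values.

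No gene passed edgeR's test between BHB and control blastocysts without pairing. That test counts differences between pairs as spread. Its estimated coefficient of variation between libraries was 0.244, against 0.159 with the replicate block. The genes with a symbol and the smallest p on the higher side were CHI3L2 (a chitinase-like secreted protein), SELENOW (selenoprotein W), MMP12 (macrophage metalloelastase) and the germ cell genes CT55 and TEX15. CHI3L2 was at 2.18 ± 1.19 CPM in control and 13.8 ± 4.75 CPM in BHB libraries (log2 fold change 2.65, SE 0.46), and MMP12 at 85.9 ± 21.4 and 158 ± 9.98 CPM (0.88, SE 0.18). On the lower side they were ANXA4 (an annexin), TAT (tyrosine aminotransferase), CTSK (the protease cathepsin K), FLRT2 (a membrane adhesion protein) and NANOG, a transcription factor of the pluripotent epiblast. NANOG was at 68.8 ± 7.04 CPM in control and 38.4 ± 11.1 CPM in BHB libraries (log2 fold change -0.84, SE 0.21). In each of these 10 genes the 3 BHB libraries did not overlap the 3 controls, and the adjusted p was 0.999 in edgeR. Groups did not overlap in 7.84% of tested genes, where chance gives 10%.

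The remaining genes of this set had log2 fold changes of 1.13 (SE 0.23) for SELENOW, 1.07 (SE 0.24) for CT55 and 1.81 (SE 0.41) for TEX15. Those of ANXA4, TAT, CTSK and FLRT2 were -0.91 (SE 0.20), -0.72 (SE 0.16), -0.86 (SE 0.20) and -2.42 (SE 0.57). FLRT2 was measured at 3.33 ± 1.28 CPM in controls and 0.61 ± 0.31 CPM with BHB. By edgeR 0 of 12732 genes passed, with 347 at an unadjusted p under 0.05 where 637 are expected by chance, and limma-voom also called 0. DESeq2's Wald test called 6 genes, chosen here after their values were seen: CHI3L2, SELENOW, MMP12, LOC512869 and LOC100140788 were higher and DDAH1 was lower with BHB. Without BHB library 2, edgeR called 1 gene, CAMK1D, as higher.

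**Figure D2:**
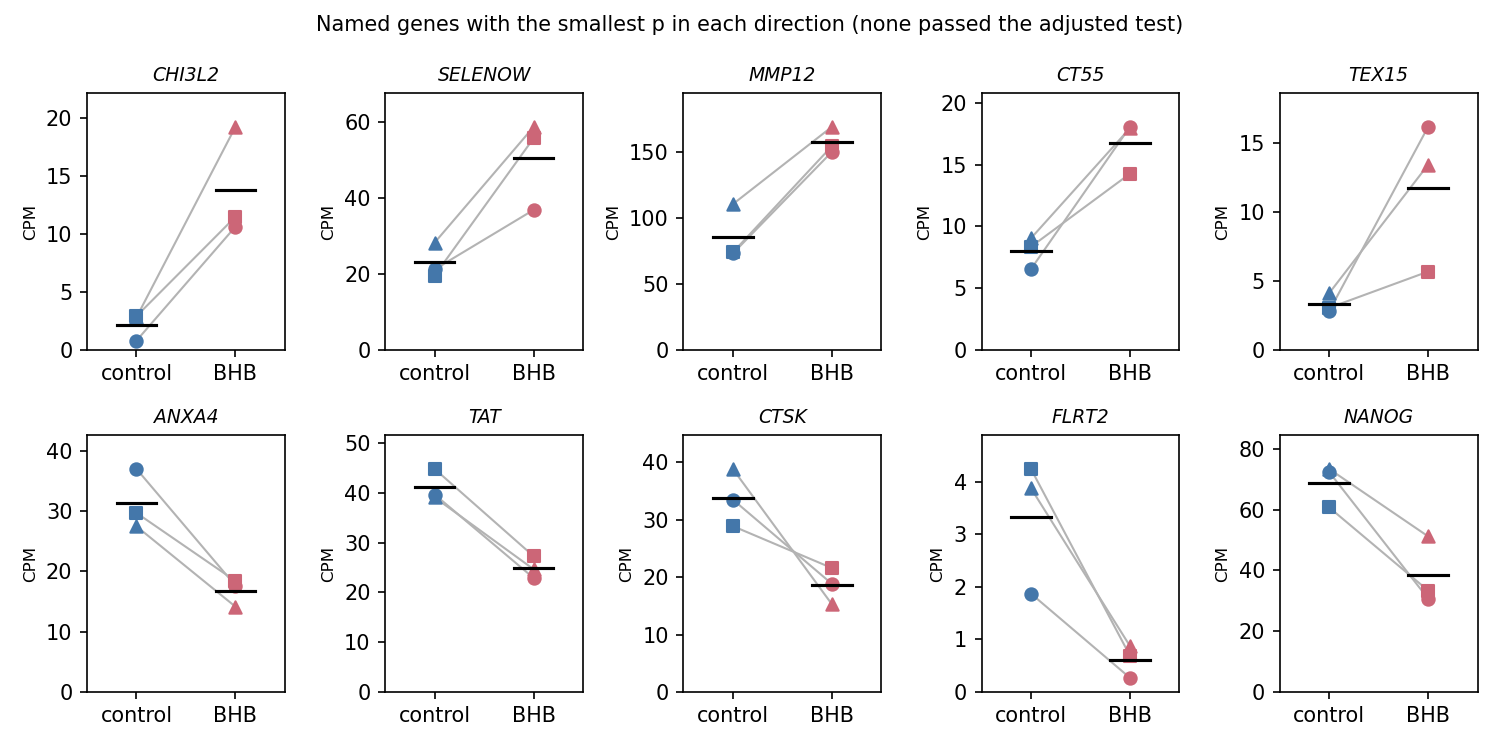
CPM (linear axes from 0) in each library for the 5 named genes with the smallest p on the higher side (top) and the 5 on the lower side (bottom); blue is control, red is BHB, symbols and grey lines mark pairs, and black bars are group means. In all 10 genes the groups do not overlap, for NANOG with means of 68.8 and 38.4 CPM. None passed edgeR's test without pairing after adjustment over all genes, whereas DESeq2's Wald test without pairing called CHI3L2, SELENOW and MMP12.

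When libraries were compared within pairs, DESeq2's Wald test called 35 genes, 17 higher and 18 lower with BHB. A test within pairs favours genes with 1 direction in 3 of 3 pairs, as all 35 had, against 30.3% of all tested genes and 25% by chance. Genes that rose in that fit included CHI3L2 (log2 fold change 2.74, adjusted p = 2.02e-05), MMP12 (0.90, adjusted p = 2.6e-05), the mitochondrial matrix protein gene C1QBP (0.82, adjusted p = 2.7e-05), SELENOW (1.12, adjusted p = 0.00048) and the homeobox gene ARGFX (1.07, adjusted p = 0.0025). TEX15, KRT5, the protease inhibitor gene SLPI and HBG, a globin gene, were also higher. Genes that fell included LRP2, the endocytic receptor megalin (-0.63, adjusted p = 9.44e-05), the urokinase gene PLAU (-0.67, adjusted p = 0.00014), NT5E, which encodes an ecto-nucleotidase that forms adenosine (-1.87, adjusted p = 0.00014), MTHFD2, an enzyme of mitochondrial folate metabolism (-0.67, adjusted p = 0.00036), and COL5A2 (-1.33, adjusted p = 0.0021). NANOG fell by 0.87 on the log2 scale (adjusted p = 0.0089), and ADA, the adenosine deaminase gene, by 0.89 (adjusted p = 0.015). HBG and BRB, another of the 35 genes, belong to families of similar genes, so their levels are uncertain. The blocked edgeR test called 0 genes at 0.05 (smallest adjusted p = 0.0624) and 11 at 0.1, all of them among the 35: CHI3L2, LOC512869, HBG, MMP12, C1QBP and SELENOW as higher, and NT5E, LRP2, COL5A2, MTHFD2 and PLAU as lower. At an unadjusted p under 0.05 the blocked edgeR test had 1044 genes where 637 are expected by chance, and the blocked DESeq2 test 595 where 641 are expected. The pairing was taken from the authors' model, and without pair 1, 2 or 3 the blocked DESeq2 test called 13, 12 or 15 genes, of which 7, 6 and 11 were among the 35. Without pair 1, 2 or 3 the blocked edgeR test called 4, 16 or 4 genes at 0.05, and its robust form called 3 with all pairs.

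Of the 31 gene lists tested, 6 were shifted down with BHB relative to other genes and 0 were shifted up under camera's preset correlation. They were the integrated stress and unfolded protein response, cytosolic ribosomal proteins, cholesterol synthesis, interferon stimulated genes, nuclear subunits of oxidative phosphorylation and mitochondrially encoded proteins. Without pairing, no member of any list passed the test over all genes or adjusted over the list alone. With an estimated correlation the adjusted p was 0.826 for each of the 6, so no call held. That test also called 0 of 2 lists shifted 1.3-fold in simulated data, so it cannot exclude shifts of that size. Within pairs, 4 of the 6 kept their call: interferon stimulated genes, cholesterol synthesis, the stress response and ribosomal proteins, with adjusted p = 0.756 to 0.827 for these 4 with an estimated correlation.

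Interferon stimulated genes, which encode antiviral proteins, had the largest shift among these lists (median log2 fold change -0.46, 15 of 18 members negative, adjusted p = 0.0214; within pairs adjusted p = 0.00145). IFI44 was at 6.66 ± 3.21 CPM in control and 2.22 ± 1.17 CPM in BHB libraries (log2 fold change -1.59, SE 0.51), and IFI6 at 28.8 ± 19.7 and 12.8 ± 8.49 CPM (-1.18, SE 0.59). The mean of the list was lower with BHB in pairs 1 and 3, by -1.08 and -0.71, and 0.09 in pair 2. The call was lost without control library 3 (adjusted p = 0.593, median 0.06) and without BHB library 1 (adjusted p = 0.70). It was also lost under the stricter filter on low counts (adjusted p = 0.372). Fits that leave out 1 library, here and below, keep its partner, so they mix pair with treatment.

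The cholesterol synthesis list had 21 of 22 members negative (median -0.22, adjusted p = 0.0214; within pairs adjusted p = 0.0031). MSMO1 and EBP, both enzymes of the late pathway, were at 454 ± 82.2 and 118 ± 31.8 CPM in controls and at 372 ± 83.0 and 94.9 ± 20.8 CPM with BHB. The list mean differed by -0.25 and -0.44 in pairs 1 and 3 and by 0.08 in pair 2. Its call was lost without control library 1 (adjusted p = 0.961, median 0.05), BHB library 2 (adjusted p = 0.0905) or BHB library 3 (adjusted p = 0.668).

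In the integrated stress and unfolded protein response list, 19 of 26 members were negative (median -0.19, adjusted p = 0.0141; within pairs adjusted p = 0.0102), and the list mean was lower in 3 of 3 pairs, by -0.28, -0.26 and -0.02. MTHFD2, a target of the stress factor ATF4, was at 271 ± 65.0 CPM in control and 170.0 ± 32.1 CPM in BHB libraries, and HERPUD1, which acts in degradation of proteins of the endoplasmic reticulum, at 47.6 ± 1.60 and 36.5 ± 4.18 CPM. Adjusted over the list alone within pairs, 4 members passed: MTHFD2, PDIA4 and the chaperones HSPA5 (log2 fold change -0.33) and HSP90B1 (-0.34). The call was lost without control library 1 (adjusted p = 0.0849), control library 2 (adjusted p = 0.293) or BHB library 1 (adjusted p = 0.142).

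Cytosolic ribosomal protein genes had a small shift (median -0.10, 59 of 71 negative, adjusted p = 0.0141; within pairs adjusted p = 0.0203), with a difference of -0.39 in pair 1 and of 0.04 and 0.07 in pairs 2 and 3. RPSA was at 568 ± 60.7 CPM in control and 472 ± 69.3 CPM in BHB libraries, and RPLP0 at 383 ± 43.5 and 314 ± 58.3 CPM; both have processed pseudogenes, so reads could be split. Nuclear oxidative phosphorylation subunits had a median of -0.08 with 60 of 77 negative (adjusted p = 0.0265), as in ATP5PF of the ATP synthase (log2 fold change -0.27, SE 0.13) and UQCRB of complex III (-0.26, SE 0.13). Mitochondrially encoded proteins had a median of -0.16 with 12 of 13 negative (adjusted p = 0.0282), as in COX2 (-0.27, SE 0.13) and ND4L (-0.27, SE 0.14). Within pairs these last lists both had adjusted p = 0.0516 and were not called, and scaling by library size alone gave adjusted p = 0.165 and 0.064 for them. The ribosomal and the nuclear lists lost their call without control library 1 (adjusted p = 0.921 for both), control library 2 (adjusted p = 0.114 and 0.179) or BHB library 1 (adjusted p = 0.732 and 0.598). The mitochondrially encoded list lost it without any library except control 3 (adjusted p = 0.0849 to 0.489).

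**Figure D3:**
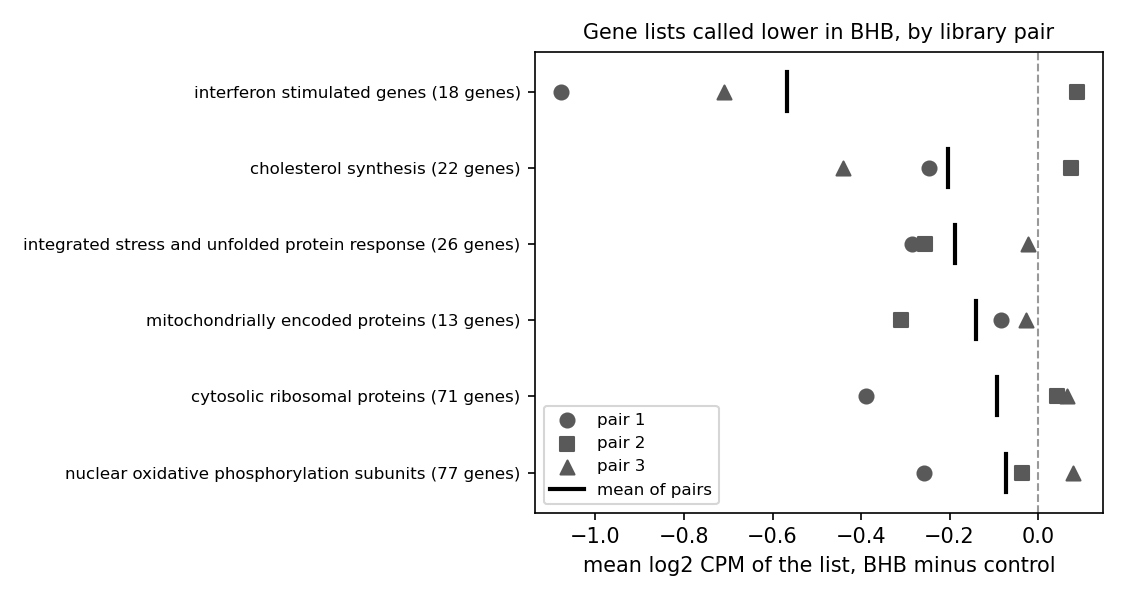
For each of the 6 lists called lower with BHB, symbols give the difference in mean log2 CPM between the BHB and the control library of each pair, and black bars the mean of the 3 pairs; the dashed line marks no difference. Interferon stimulated genes run from -1.08 in pair 1 to 0.09 in pair 2, and the stress response and the mitochondrially encoded list lie below 0 in 3 of 3 pairs.

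Genes that use or carry ketone bodies did not pass. Of 8 tested members of that list, 5 were negative (median -0.17, adjusted p = 0.423). The monocarboxylate transporter SLC16A1 was at 825 ± 156 CPM in control and 686 ± 94.2 CPM in BHB libraries, lower in 3 of 3 pairs, and the related SLC16A7 at 91.0 ± 75.6 and 53.3 ± 30.9 CPM. SLC16A7 passed within pairs when adjusted over the list alone, but without pairing its log2 fold change of -0.77 (SE 0.56) turned to 0.16 without control library 1. OXCT1, which activates ketone bodies for oxidation, was at 80.2 ± 28.1 and 68.5 ± 17.9 CPM, and BDH1, the mitochondrial BHB dehydrogenase, at 1.86 ± 0.26 and 2.00 ± 1.08 CPM (log2 fold change 0.11, SE 0.50). The direction of OXCT1 turned without control library 1 (log2 fold change -0.23 with all libraries, 0.10 without it) and that of BDH1 without BHB library 2 (-0.39). Both fits likewise kept the partner of the library left out. Among energy lists, the tricarboxylic acid cycle had 20 of 24 members negative (median -0.11, adjusted p = 0.236), with PDK3 at a log2 fold change of 0.39 (SE 0.17). Glycolysis had a median of -0.06 (adjusted p = 0.845), with PFKP at 0.82 (SE 0.36) and ENO1 at -0.41 (SE 0.19); ENO1 was the 1 member past the threshold within pairs adjusted over the list alone. Fatty acid oxidation (median -0.06, adjusted p = 0.845) held ACSL4 at 0.26 (SE 0.22) and HADH at -0.22 (SE 0.20). Fatty acid synthesis and lipid droplets (median -0.05, mean 0.03, adjusted p = 0.996) held the fatty acid binding protein gene FABP5 at -0.35 (SE 0.12) and the lipid receptor gene CD36 at 0.63 (SE 0.31).

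Lineage lists did not shift in 1 direction. Within pairs, trophectoderm (adjusted p = 0.0298) and primitive endoderm markers (adjusted p = 0.0408) passed fry for change in either direction. Trophectoderm markers had 10 of 22 members positive (median -0.03, adjusted p = 0.865), with KRT19 at 345 ± 198 CPM in control and 195 ± 59.5 CPM in BHB libraries and TFAP2C at 215 ± 55.0 and 278 ± 16.6 CPM. Within pairs, adjusted over the list alone, 4 of these 22 passed: the keratins KRT8 (log2 fold change -0.39), KRT18 (-0.38) and KRT19 (-0.71) were lower and TFAP2C (0.40) was higher. CDX2, which specifies trophectoderm, had a log2 fold change of 0.32 (SE 0.39) and GATA3 of -0.02 (SE 0.16). Inner cell mass and epiblast markers had 11 of 17 positive (median 0.10, adjusted p = 0.570). Within pairs, adjusted over the list alone, NANOG passed as lower and KLF17 as higher (18.5 ± 3.52 CPM in control, 30.5 ± 5.44 CPM in BHB libraries). POU5F1, another pluripotency factor, was at 292 ± 15.6 and 290.2 ± 29.2 CPM. Primitive endoderm markers had 13 of 20 positive (median 0.08, adjusted p = 0.574), with COL4A2 at a log2 fold change of 0.62 (SE 0.27) and GATA6 at 0.13 (SE 0.16), and GATA4 at 2.52 ± 0.60 CPM in control and 1.25 ± 0.49 CPM in BHB libraries. Trophoblast secreted products had 7 of 8 negative (median -0.32, adjusted p = 0.423), with the steroid enzyme genes HSD3B1 at -0.33 (SE 0.21) and CYP11A1 at -0.21 (SE 0.24). Tight junction and blastocoel genes had a median of -0.06 (adjusted p = 0.652), with AQP11 at -0.32 (SE 0.16) and TJP3 at 0.27 (SE 0.15).

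BHB can inhibit histone deacetylases, and chromatin genes were therefore among the lists. None of these chromatin lists passed. The values are RNA levels and do not measure enzyme activity or histone acetylation, so they cannot test such inhibition. Histone deacetylases and sirtuins had a median of 0.02 (adjusted p = 0.845). HDAC1, HDAC2, HDAC3 and HDAC5 had log2 fold changes of 0.05 (SE 0.15), 0.24 (SE 0.16), -0.10 (SE 0.19) and 0.33 (SE 0.20). Acetyltransferases and acyl readers (median 0.05, adjusted p = 0.652) held EP300 at 0.04 (SE 0.18), NCOA1 at -0.27 (SE 0.17) and YEATS2 at 0.29 (SE 0.20). The DNA methylation machinery (median -0.02, adjusted p = 0.576) held the methyltransferases DNMT1 at 0.18 (SE 0.23), DNMT3A at -0.28 (SE 0.21) and DNMT3B at -0.10 (SE 0.19), with the demethylation enzyme TET3 at -0.57 (SE 0.26) and MBD2 at -0.67 (SE 0.39). Histone methylation genes (median 0.10, 22 of 33 positive, adjusted p = 0.461) held KDM4A at 0.31 (SE 0.18) and EZH1 at -0.44 (SE 0.27). Imprinted genes had a median of -0.12 (adjusted p = 0.698), with MEST at 3.15 ± 0.75 CPM in control and 7.46 ± 2.87 CPM in BHB libraries and IGF2R at 25.3 ± 3.57 and 18.8 ± 2.14 CPM. Within pairs the imprinted list passed fry for change in either direction (adjusted p = 0.0408). FOXO3, a stress-responsive transcription factor, had a log2 fold change of -0.40 (SE 0.27).

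Apoptosis and p53 response genes had 17 of 25 members positive (median 0.13, adjusted p = 0.0988), with BAD at 0.57 (SE 0.23) and GADD45B at 0.46 (SE 0.23). Inflammasome and NF-kB genes (median 0.10, 9 of 12 positive, adjusted p = 0.301) held the cytokine gene IL6 at 0.78 (SE 0.25) and NLRP3 at 0.82 (SE 0.42). The antioxidant response (median -0.13, adjusted p = 0.389) held SRXN1 at -1.01 (SE 0.29) and GPX3 at -0.77 (SE 0.46), and the heat shock response (median -0.05, adjusted p = 0.546) held HSP90AA1 at -0.27 (SE 0.14) and HSPH1 at -0.29 (SE 0.18). S phase genes (median 0.04, adjusted p = 0.546) held SLBP at 0.51 (SE 0.24) and UNG at 0.27 (SE 0.15). G2 and M phase genes (median 0.06, adjusted p = 0.429; adjusted p = 0.0247 as higher without control library 2) held CCNA2 at 0.28 (SE 0.13) and NDC80 at 0.28 (SE 0.15). Mitochondrial ribosomal proteins (median -0.01, adjusted p = 0.852) held MRPL3 at -0.24 (SE 0.12) and MRPL32 at 0.34 (SE 0.17). Markers of other cells and stages did not shift in 1 direction either, though cumulus and granulosa markers passed fry for change in either direction within pairs (adjusted p = 0.0408). Cumulus and granulosa markers had a median of 0.00 and a mean of -0.10 (adjusted p = 0.664), with VIM at -1.34 (SE 0.40) and COL3A1 at 1.09 (SE 0.55), and VIM passed within pairs adjusted over the list alone. Oocyte transcripts (median -0.19, adjusted p = 0.546) held OOSP2 at -1.54 (SE 0.61) and UCHL1 at 0.28 (SE 0.26), and sperm markers (median -0.05, adjusted p = 0.908) held CRISP2 at -0.60 (SE 0.32) and ODF2 at 0.17 (SE 0.16). CD68 was the 1 gene of the fixed list of blood and immune markers in the table (1.90 ± 0.51 CPM in control and 2.61 ± 0.17 CPM in BHB libraries), 0 Y-linked genes were in it, and of the X inactivation list RLIM was at -0.21 (SE 0.15) and XIST at 0.29 (SE 0.32).

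The authors' deposited table called 646 genes at an adjusted p under 0.05, 253 higher and 393 lower with BHB. Its p-values were those of a joint test of library pair and treatment with 3 degrees of freedom. In the refit, the pair part of the statistic was larger than the treatment part in 599 of the 646 genes and smaller in 47. The treatment part made up a median of 10.9% of the statistic in the 646 genes and of 17.2% in all genes of the table. DESeq2's likelihood ratio test of treatment given pair called 32 genes, all among the 646, while 399 of the 646 had an unadjusted treatment p of at least 0.05. The pair test alone called 540 of the 646. Of the 35 genes called by the blocked Wald test, 34 were in the authors' calls, and so were all 11 genes of the blocked edgeR test at 0.1. The deposited statistic contains the treatment part, from the same counts and pairs. These overlaps, and that of the 32 genes, therefore follow largely by construction and are no separate support. COL5A2 is an example of a gene that differed both ways: it was called between pairs and, within pairs, fell in 3 of 3. The deposited adjusted p-values were not a plain Benjamini-Hochberg adjustment of the deposited p-values, which gives 678 genes at 0.05.

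**Figure D4:**
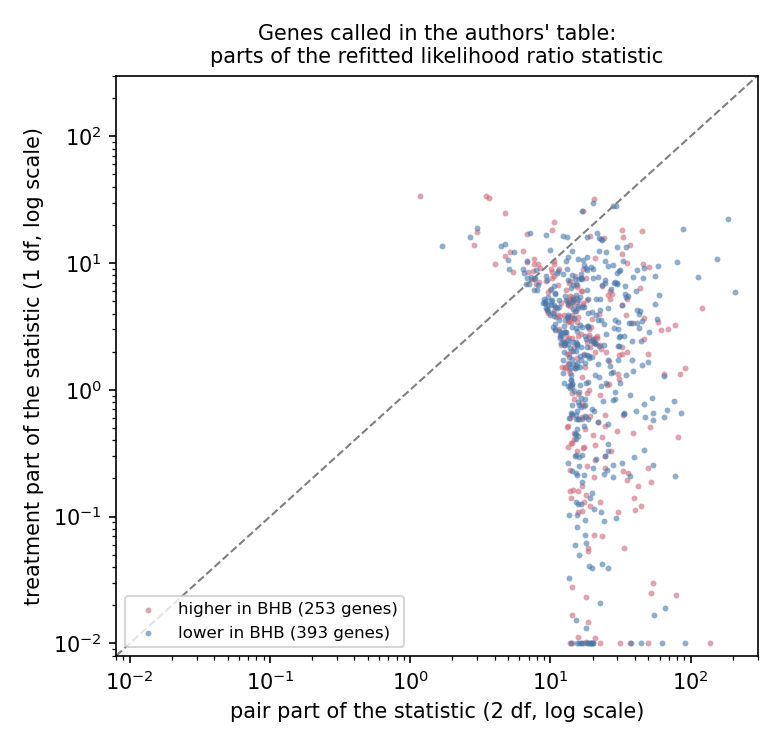
Each point is 1 of the 646 genes called in the authors' deposited table, with the pair part of the refitted likelihood ratio statistic on the x axis and the treatment part on the y axis (log scales, treatment parts under 0.01 drawn at 0.01); red genes were higher and blue genes lower with BHB, and the dashed line marks equal parts. Below the line lie 599 genes, and 47 lie above it.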

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

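The replicate block, the fits built on it and the thinning of libraries were chosen after seeing the data; the other settings were planned. The count of 0 genes held under 3 other scalings, both other filters, limma-voom, robust edgeR, an adjusted p under 0.1 and a fold limit of 1.2. DESeq2's Wald test gave 6 genes (5 higher, 1 lower). Leaving out each library gave 0 to 1 genes called and 0 to 1 higher. With the replicate block, edgeR gave 11 genes at 0.1 (6 higher, 5 lower) and robust edgeR 3 at 0.05 (2 and 1). The blocked DESeq2 test gave 35 (17 and 18). Without pairs 1, 2 and 3 the blocked edgeR test gave 4 (1 and 3), 16 (7 and 9) and 4 (3 and 1), and the blocked DESeq2 test 13 (7 and 6), 12 (4 and 8) and 15 (10 and 5). With blocked edgeR and limma-voom the count stayed 0 at 0.05. For the lists, camera with an estimated correlation and fry each gave 0 shifted down, with the replicate block too; at the preset correlation the block left 4 lists down and changed no other call of a list. Leaving out each library gave 1 to 5 lists down and 0 to 1 up. Scaling by library size alone gave 4 down, and thinning to the smallest total gave 6. The authors' table held 830 genes at an adjusted p under 0.1 and 19 with an absolute log2 fold change of at least 1 (10 higher, 9 lower). The covariate of Y-linked genes was not run. The cause of these changes was not tested, except that a stricter limit on fold change leaves fewer genes by construction.

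Of 2075 values of 87 named genes under the alternatives, 2003 kept direction and side of the threshold and 24 passed it. The remaining 48, in 15 genes, changed sign with none past the threshold, and the cause was not tested. Fits without 1 library keep its partner, so they mix pair with treatment. Over left-out libraries, log2 fold changes ran from -1.35 to 0.16 for SLC16A7, -0.49 to 0.012 for CYP11A1, -0.25 to 0.50 for XIST, -0.39 to 0.41 for BDH1, -0.46 to 0.10 for OXCT1, -0.050 to 0.56 for CDX2, -0.10 to 0.15 for GATA3, -0.093 to 0.043 for POU5F1, -0.0069 to 0.25 for GATA6, -0.054 to 0.19 for HDAC1, -0.21 to 0.11 for HDAC3, -0.016 to 0.35 for DNMT1, -0.25 to 0.018 for DNMT3B and -0.14 to 0.14 for EP300. Library size alone gave 0.050 for GATA3 and 0.056 for POU5F1, limma-voom -0.023 for BDH1 and the blocked DESeq2 test -0.0069 for BDH1. With the replicate block and pair 1 left out, edgeR and DESeq2 gave 0.032 and 0.029 for CRISP2, 0.20 and 0.20 for GATA3, 0.053 and 0.049 for POU5F1, 0.098 and 0.094 for HDAC3, 0.051 and 0.049 for DNMT3B and -0.11 and -0.11 for EP300. Without pair 2 they gave 0.12 and 0.11 for CYP11A1, -0.40 and -0.42 for BDH1 and -0.0034 and -0.0085 for HDAC1, and DESeq2 -0.0028 for DNMT1. Without pair 3 they gave -0.27 and -0.28 for XIST, 0.017 and 0.0045 for POU5F1 and 0.050 and 0.038 for DNMT3B. List medians ran from -0.70 to 0.058 for interferon stimulated genes and from -0.40 to 0.054 for cholesterol synthesis over left-out libraries. Without pair 1 they were 0.022 for nuclear oxidative phosphorylation and 0.057 for ribosomal proteins.

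Library size alone moved the median of all genes from -0.005 to 0.06, and 10 of 31 list medians changed sign under another scaling, none of them of a list called lower. At this depth, edgeR without a block called 40.8% of simulated 2-fold changes without pair differences and 12.2% with them, where the replicate block called 69.4%; 1.5-fold changes were called in 6.25%, 2.08% and 31.3%.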

Other observations

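The tests of the authors' p-values, of list members that vary together, of other pairings and of lineage genes were chosen after their results had been seen; the tests of depth and of other splits were chosen after the data had been seen but before their own results, except that repeating the thinning for the genes called between pairs was decided after a single thinning had been seen.

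The genes that differed between pairs included lineage genes, which made up 18 of the 524. Of 8 tested trophoblast secreted products 4 were called between pairs, as were 6 of 22 trophectoderm markers, 5 of 20 primitive endoderm markers and 3 of 17 inner cell mass markers. Cholesterol synthesis had 4 of 22, with a list mean 0.39 above the average of all libraries in pair 1 and 0.19 and 0.20 below it (-0.19 and -0.20) in pairs 2 and 3. Among other lists, fatty acid synthesis and lipid droplets had 5 of 25, ketone body genes 2 of 8 and mitochondrially encoded proteins 2 of 13. Nuclear oxidative phosphorylation had 0 of 77, mitochondrial ribosomal proteins 0 of 76 and S phase genes 0 of 30. Tested for change in either direction within pairs (fry), trophectoderm markers (adjusted p = 0.0298), primitive endoderm markers, imprinted genes, cumulus markers and the stress response (adjusted p = 0.0408 for each) passed. XIST was at 82.4, 117 and 88.5 CPM in control libraries and 80.3, 81.0 and 190.1 CPM in BHB libraries 1 to 3.

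The first pattern is that the authors' deposited table called 646 genes where tests of treatment called 0 to 35. The pair part of the refitted statistic exceeded the treatment part in 92.7% of the 646 genes, against 79.6% of all genes. A difference between DESeq2 and edgeR as the whole reason is argued against by DESeq2's own likelihood ratio test of treatment given pair, which called 32 genes. The pair test alone called 540 of the 646 genes. An unadjusted treatment p of at least 0.05 was found in 399, and the pair test called 384 of these. Most of the 646 genes would thus have passed on differences between pairs alone. Whether some also respond to BHB by less than these tests can see stays open.

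The second pattern is the 6 lists shifted down with BHB. Lower depth of the BHB libraries is argued against, since 6 of 6 lists stayed called after all libraries were thinned to the smallest total. The list mean was lower with BHB in 3 of 3 pairs in 2 of the 6 lists, the stress response and the mitochondrially encoded list, with differences of only -0.02 and -0.03 in pair 3. Tests that allow for members varying together called 0 of the 6: the adjusted p with an estimated correlation was 0.826 for each, and 0.756 to 0.827 within pairs, and fry for 1 direction called 0 lists with and without the replicate block, though the stress response passed fry for change in either direction within pairs (adjusted p = 0.0408). In simulated data camera with an estimated correlation called 0 and fry 1 of 2 lists shifted 1.3-fold. These tests therefore cannot exclude a shift of that size. Within pairs the estimated correlation was 0.22 to 0.87 in the other lists but -0.015 in the stress response, an estimate that rests on few libraries. Members that vary together between libraries for other reasons may account for the shift of those other lists. For the stress response, members varied together only without the block (0.16), so this does not account for its lost call within pairs. A response to BHB stays open.

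The third pattern is the likeness of the libraries within a pair. Other pairings of control with BHB libraries called at most 80 genes between pairs, against 524. The 80 came from the pairing that kept pair 1 and swapped pairs 2 and 3, and each remaining pairing called 0. By the chi-square of counts over its degrees of freedom, BHB library 2 was nearer to control 3 (9.63) than to its partner, control 2 (10.9). Depth is argued against as the reason, since it differed little between pairs (mean totals of 7637419, 7600570 and 7308690 counts in pairs 1 to 3). On average 87.2% (SD 7.03, range 76.1 to 97.9) of the 524 genes stayed called over 10 thinnings to the smallest total. That smallest total was 6440732 counts, so the thinning removed few counts and is a weak test. Genes of the 4 lineage lists were called more often than other tested genes (18 of 67 against 506 of 12665, odds ratio 8.82, Fisher's exact test p = 1.23e-10, two-sided, with genes not independent), which is consistent with pools that differed in lineage composition or stage, though lipid and ketone body lists had shares in the same range and most of the 524 genes are in no lineage list. Parentage and day of culture were not tested.

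Splits of the 6 libraries into 3 and 3 are 10 in number, too few for a share under 0.05. The real split gave 0 genes, which all 10 splits reached, and the highest other gave 1. It shifted 6 lists, the most in 1 split, and the highest other shifted 5. Among the 4 splits that part all 3 pairs, also too few, 1 split (the real one) gave as many as 35 genes with the blocked DESeq2 test and the highest other gave 13; for blocked edgeR at 0.1 the values were 11 in 1 split and 0.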
